A study of Mus musculus with 18 samples.

How the data were processed

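Circular RNAs were measured in whole brains of male mice of 3 genotypes with 3 replicates each, on Illumina and on Oxford Nanopore (ONT) sequencers, which makes 18 samples. Per the labels' protocols, 5 ug of total RNA was treated with RNase R, reverse transcribed by rolling-circle priming with random hexamers and amplified as cDNA for 14 PCR cycles. For Illumina, 5 ng of this cDNA was fragmented by tagmentation and amplified for 9 further cycles, with paired reads of 150 nt and an insert of about 350 bp. For ONT, 100 ng of the same kind of cDNA went into a ligation library. Files of 9 Illumina libraries and of 8 ONT libraries were used, because wild type replicate 1 has no ONT file here. A second Illumina table, from CIRI2, was present for 8 libraries and not for Adar1-2KO replicate 1.

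Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with BWA 0.7.17 to GRCm39 (mm39) and circular RNAs were quantified with CIRIquant 1.1.2. The authors' CIRIquant tables list counts of back-splice reads and of forward-splice reads per circle, per the file headers. The deposited CIRIquant tables also hold a junction ratio, a fraction from 0 to 1 that equals the back-splice reads of both ends over these plus the forward-splice reads. A deposited expression value per circle is in CPM, the back-splice reads of both ends over mapped reads. In the 3 Adar1-2KO tables the deposited values stand 1 column to the right of their headers, which was found from the values and corrected. The deposited CIRI2 tables hold counts of junction reads from 2 upward, and the deposited ONT tables hold counts of reads from 2 upward, from a caller that the labels do not name. The authors compared each mutant with wild type with DESeq2 2.11.40.8, and their 2 deposited tables give a base mean (a normalized signal), a log2 fold change, its standard error and a Wald score, a p-value and an adjusted p-value. The authors' Adar2KO table holds only 772 circles, all with an unadjusted p-value under 0.05, and the Adar1-2KO table holds 160909.

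The circle was the unit, defined by chromosome, start and end on GRCm39. Gene names were those of the deposited tables. Of 208914 circles, 9.10% had no gene and 6.43% overlapped several genes. For these, predicted genes and small RNAs were set aside where exactly 1 other name remained, and 1.70% kept several names. The labels name no step that marks strand, so the gene is uncertain for circles of overlapping or antisense genes.

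Circles with at least 5 reads in at least 3 libraries were tested, 38297 on Illumina and 10367 of 166212 on ONT. Back-splice counts summed per host gene were tested for 8650 of 15913 genes. The test was the two-sided quasi-likelihood F-test of edgeR 4.0.16 with TMM scaling, all libraries of a platform in 1 fit, and Benjamini-Hochberg adjustment at 0.05. All values called CPM below are counts relative to the back-splice reads of the library after TMM scaling, and SE is the standard error of the fitted log2 fold change. The circular share was tested with limma 3.58.1 on the log2 of back-splice over forward-splice reads with a pseudocount of 0.5, for 6353 circles with at least 20 reads, both kinds summed, in every library. Single values per library were compared by two-sided exact permutation tests of group means, which cannot go below 0.1 with 3 against 3, as a family of 18 tests.

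Gene lists of 17 kinds were tested on the host gene fit with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. They held the genes altered in these mice, hosts of known recoding sites, splicing and circular RNA regulators, double-stranded RNA sensing and interferon genes, glutamatergic postsynaptic, presynaptic and GABAergic genes, voltage-gated channels and known abundant hosts of brain circles. The other lists held markers of oligodendrocyte lineage, astrocytes, microglia, endothelial cells and pericytes, ependyma and choroid plexus, and of cerebellum, striatum, and cortex and hippocampus. The first list had fewer than 5 measured members and was described without a test.

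The genes named were chosen by rule. For each comparison and platform these were the up to 10 largest rises and falls among circles that passed and whose 2 groups did not overlap, and, where fewer than 10 qualified, the up to 5 of lowest p that did not pass, given as values. The circles with most reads of Adarb1, Adar, Ifih1 and Gria2, the 10 most abundant circles of wild type brain and up to 4 host genes per list were added. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Another 3 alternatives were added after the data were seen, a fit of features listed in every library, a fit of the libraries that share flow cell 1 and platform agreement with 1 library left out on both platforms.

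The alternatives were a threshold of 0.1, DESeq2 1.42.0, DESeq2 size factors in edgeR, library sizes from mapped reads, at least 10 reads in place of 5, no filter, fits of 2 genotypes, the replicate number as a block, CIRI2 counts, and leaving out each library in turn. Where 1 library of a group was left, it was assumed to vary like those of the other groups. Flow cells were read from the read names in the CIRI2 tables. The 3 wild type libraries came from 1 lane of flow cell 1, as did Adar1-2KO replicate 2 and 87.4% of the junction reads of Adar2KO replicate 3 from another lane of it. Adar2KO replicates 1 and 2 came mainly from flow cell 2, Adar1-2KO replicate 3 from flow cells 6 and 7, and the flow cell of Adar1-2KO replicate 1 is unknown.

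The steps were tested on simulated counts drawn from the mean of each feature over all libraries of a platform, with their library sizes and fitted spread. In 1 draw, 100 features were changed 4-fold and 100 changed 16-fold in Adar1-2KO, which was tested against wild type. For circles on Illumina, 1% of the former and 24% of the latter were called, with 16 calls among the unchanged of 38297 circles. For host genes 41% and 58% were called, with 4 such calls of 8650, and for ONT circles 5% and 42%, with 3 such calls of 10367. Depth ran from 1516772 to 4308264 back-splice reads per Illumina library and from 186594 to 673705 reads per ONT library. Reads carry no molecular identifiers, so intervals given below cover counting error only. A circle that a table leaves out was taken as 0 reads and is written as listed in none of the libraries. Programs were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Flanking sequence of the circles was not analysed here.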

Results

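Circular RNAs, which are closed by a back-splice junction and withstand RNase R, were sequenced from whole brains of male mice aged 3 to 4 months. Wild type mice were set beside 2 mutants of the adenosine-to-inosine RNA editing enzymes. Adar2KO mice lacked ADAR2, the enzyme encoded by Adarb1, and carried a Gria2 allele that encodes the edited form of this AMPA receptor subunit. Adar1-2KO mice had the same changes, an ADAR1 (Adar) without editing activity and no Ifih1, the sensor MDA5 of double-stranded RNA. Each genotype had n = 3 libraries on Illumina and n = 3 on ONT, except for wild type with 2 on ONT. The labels give C57BL/6J as the strain background.

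On Illumina, wild type replicates 1, 2 and 3 held 3169249, 2207905 and 1516772 back-splice reads over 76743, 65365 and 54244 circles. Adar2KO replicates held 2659618, 2273787 and 3109401 reads over 71505, 66561 and 67227 circles. Adar1-2KO replicates 1 and 2 held 3385000 and 2181700 reads over 70671 and 59281 circles. Adar1-2KO replicate 3 had the most reads of the 9, 4308264, and the fewest circles, 21736. On ONT, wild type replicates 2 and 3 held 205273 and 186594 reads over 25085 and 22347 circles, and the Adar2KO replicates 364380, 447592 and 425390 reads over 35772, 47174 and 41111 circles. Adar1-2KO replicates 1, 2 and 3 held 448511, 296959 and 673705 ONT reads over 46818, 33077 and 23441 circles. Replicate 3 also stood apart in Spearman correlations of circle abundance on Illumina, 0.444 to 0.468 with the other libraries, against 0.549 to 0.643 among those.

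**Figure D1:**
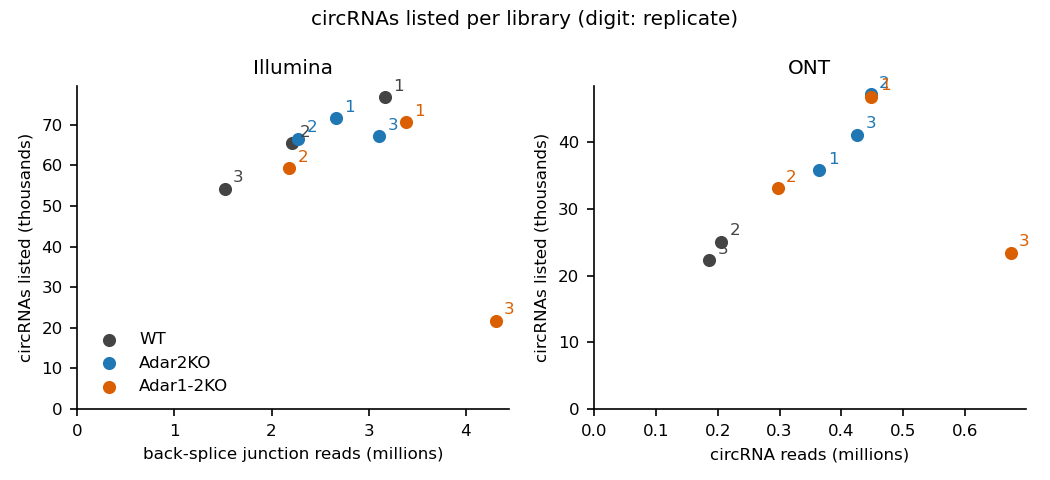
Number of circular RNAs listed (vertical axis) against back-splice reads on Illumina or reads on ONT (horizontal axis) per library, coloured by genotype, with the replicate number at each point. Adar1-2KO replicate 3 listed 21736 circles from 4308264 reads on Illumina and 23441 circles from 673705 reads on ONT.

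The genes altered in these mice came first. The labels do not give the deleted exons, so circles of these genes check little beyond the split of mutants from wild type. The Adarb1 circle with most reads (chromosome 10, 77130537 to 77148360, exons) was listed in none of the 3 wild type libraries. It had 177, 239 and 236 reads in Adar2KO and 288, 134 and 724 reads in Adar1-2KO. On ONT the same circle had 0 reads in both wild type libraries, 41, 38 and 27 in Adar2KO and 27, 18 and 66 in Adar1-2KO. The main Gria2 circle (chromosome 3, 80634139 to 80648505) had 498, 301 and 170 reads in wild type, 75, 111 and 175 in Adar2KO and 86, 85 and 104 in Adar1-2KO. The main Adar circle (chromosome 3, 89642149 to 89647585) had 71, 41 and 11 reads in wild type, 30, 21 and 23 in Adar2KO and 27, 0 and 6 in Adar1-2KO. Ifih1 had 1 circle, with 2 reads in Adar2KO replicate 2 and none in the other libraries, too few for a statement.

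Among circles that Illumina listed in wild type brain, the circle of exon sequence of Zfp609 (chromosome 9, 65701904 to 65702777), a zinc finger gene, was the most abundant at 18577 ± 2658 CPM (SD, n = 3). Circles of Gigyf2 at 11664 ± 514 CPM, Hdgfl3 at 7759 ± 1387 CPM, Rims2 at 7326 ± 543 CPM and Rbm4 at 7068 ± 9.51 CPM followed. Circles of Anks1b, Zfp148, Kat6b, Rims1 and Elf2 completed the 10 most abundant, between 5797 and 6433 CPM. Rims1 and Rims2 encode scaffolds of the presynaptic active zone. These 10 circles took 7.56%, 8.01% and 8.34% of the back-splice reads of the 3 wild type libraries. None of them passed edgeR's test in either mutant, with log2 fold changes from -0.40 to 0.34.

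The total yield of circles was compared to see whether the genotypes differed in how many were listed. Adar2KO libraries listed 68431 ± 2683 circles (SD, n = 3), wild type 65451 ± 11250 and Adar1-2KO 50563 ± 25606. Back-splice reads, as CPM of mapped reads, were 12007 ± 2789 in wild type, 13684 ± 1806 in Adar2KO and 15646 ± 2124 in Adar1-2KO. Circles of exon class made up 83.5 ± 1.26%, 82.3 ± 0.547% and 84.3 ± 3.32% of circles in wild type, Adar2KO and Adar1-2KO and intergenic circles 4.82 ± 0.594%, 5.36 ± 0.478% and 4.55 ± 1.38%. The share of intron circles was 10.5 ± 0.508% in wild type, and the mutants differed from it by 0.540 and -0.434 percentage points. The median circular share, the back-splice reads of both ends over these plus the forward-splice reads, was 26.2 ± 2.17%, 27.1 ± 1.06% and 30.6 ± 4.34%. With CIRI2 counts the mutants differed from wild type in it by 0.333 and 7.18 percentage points, with 2 Adar1-2KO libraries. None of these differences passed. The lowest of the 18 two-sided exact permutation p was 0.2, with an adjusted value of 0.6, in a design that allows no p under 0.1. Without Adar1-2KO replicate 3 the difference of Adar1-2KO from wild type went from -14888 to -475 circles and from 4.39 to 1.91 percentage points of median circular share. There the exon difference of Adar1-2KO from wild type turned from 0.794 to -1.06 percentage points, that of introns from -0.434 to 0.479 and that of intergenic circles from -0.270 to 0.493.

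Adar2KO against wild type compared brain circles without ADAR2, and with the Gria2 allele for the edited form, with those of wild type. It cannot tell loss of editing from this allele. The groups also differ in part in flow cell, as Adar2KO replicates 1 and 2 came mainly from flow cell 2. Few circles were called, 6 up and 2 down of 38297. In the simulated counts 1% of circles changed 4-fold and 24% of those changed 16-fold were called. The same draw gave 6 calls for Adar2KO against wild type, where nothing was changed, and 40 draws with no difference gave 7.38 on average. Other splits of the real libraries gave at most 1 call. The 8 calls may thus include false ones, and the count does not tell how many circles changed. Circles of Dennd1b, an exchange factor of Rab35, of Gabra2, the alpha2 subunit of GABA-A receptors, of Adarb1 itself and of Chchd6, a part of the mitochondrial cristae complex, rose from being listed in none of the wild type libraries. The circle of Fbxo42, an F-box protein of ubiquitin ligases, rose from 222 ± 28.1 to 1112 ± 113 CPM, a log2 fold change of 2.32 ± 0.31 (SE, n = 3), and it also rose on ONT. Circles of Wdr49, a WD repeat gene, and of Cabin1, a calcineurin inhibitor, fell to being listed in none of the Adar2KO libraries.

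The Dennd1b circle (chromosome 1, 138967738 to 138969781) had 251 ± 15.7 CPM in Adar2KO (edgeR adjusted p = 0.000107). The Gabra2 circle (chromosome 5, 71163450 to 71171979) had 92.9 ± 15.8 CPM, the Adarb1 circle 89.0 ± 19.2 CPM and the Chchd6 circle (chromosome 6, 89544569 to 89546394) 74.2 ± 23.7 CPM, each with an edgeR adjusted p of 0.00101. ONT read the Dennd1b circle in wild type too, at 260 CPM against 556 CPM in Adar2KO, and the Chchd6 circle with a log2 fold change of 0.46 without passing. It read the Gabra2 circle at 91.4 CPM in Adar2KO and in neither wild type library. The Fstl5 circle (chromosome 3, 76389532 to 76443671) rose from 0.828 ± 0.451 to 68.3 ± 17.3 CPM (edgeR adjusted p = 0.0311), a ratio of 87.9 with a 95% counting interval from 37.4 to 272. ONT read it at 58.8 CPM in Adar2KO and in neither wild type library, without passing. The Fbxo42 circle (chromosome 4, 140895024 to 140907843) had an edgeR adjusted p of 0.0172. Its Adar1-2KO level was 211 ± 89.3 CPM. The Wdr49 circle (chromosome 3, 75265654 to 75304408) fell from 294 ± 49.5 CPM (edgeR adjusted p = 0.0339). The Cabin1 circle (chromosome 10, 75520126 to 75535929) fell from 80.0 ± 3.25 CPM (edgeR adjusted p = 0.0346), while ONT read it at 65.5 CPM in wild type and 104 CPM in Adar2KO.

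Circles of lowest p that did not pass were given as values. A circle of Atp6v1h, a subunit of the proton pump of vesicles, had a log2 fold change of 2.36, and a longer Gabra2 circle (71163450 to 71192140) had 1.63. A circle of Mettl6, a tRNA methyltransferase, stood at 1136 ± 114 CPM in wild type and 446 ± 54.6 in Adar2KO, and its edgeR adjusted p was 0.131. A Gm42339 circle had a log2 fold change of -2.17. A circle of Lrba (64.2 ± 18.1 CPM in wild type) and one of Ccser2 (97.7 ± 23.9 CPM) were listed in none of the Adar2KO libraries, with edgeR adjusted p of 0.0721 and 0.398. ONT listed both in all 3 Adar2KO libraries, at 42.8 and 58.1 CPM against 76.0 and 111 CPM in wild type. Summed per host gene, Chchd6 (5.71 ± 0.72), Fbxo42 (2.18 ± 0.30) and Gabra2 (1.90 ± 0.18) rose, and Wdr49 (-5.55 ± 0.50), Ccser2 (-2.37 ± 0.31) and Gm42339 (-2.10 ± 0.33) fell, all as log2 fold changes with SE, 3 up and 3 down of 8650. Gabra2 as a host rose from 146 ± 5.82 to 544 ± 38.5 CPM and Wdr49 went from 365 ± 81.2 to 7.79 ± 3.56 CPM, both with an edgeR adjusted p of 0.000682. These 2 calls were kept without any 1 of the libraries. Those of Fbxo42 and Ccser2 were lost without any wild type library or Adar2KO replicate 1 or 2, that of Chchd6 without Adar2KO replicate 1 or wild type replicate 1 or 3 and that of Gm42339 without any but Adar2KO replicate 3 or Adar1-2KO replicate 3 (edgeR adjusted p up to 0.166, 0.107, 0.0715 and 0.225).

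At an unadjusted p under 0.05 stood 697 of 38297 circles and 153 of 8650 host genes. Both lie below the share of 0.05 that evenly spread p would give with no change. DESeq2 called 34 circles and 15 host genes. The count of circles ran from 4 without wild type replicate 2, Adar2KO replicate 1 or 3 or Adar1-2KO replicate 1 to 20 without Adar1-2KO replicate 3, and that of host genes from 2 without wild type replicate 3 or Adar2KO replicate 1 to 11 without Adar1-2KO replicate 3. Of the 8 called circles 6 were listed in none of the libraries of 1 group. The calls of Dennd1b, Gabra2, Adarb1 and Chchd6 were kept without any 1 of the 9 libraries, each with 0 reads taken for wild type in every fit. Those of Fbxo42 and Wdr49 were lost without any 1 library except Adar1-2KO replicate 2 or 3 (adjusted p up to 0.227 and 0.229), that of Fstl5 without any but Adar1-2KO replicate 3 (up to 0.409), and that of Cabin1 without Adar1-2KO replicate 1 or any Adar2KO library (up to 0.197), all by edgeR. Without a wild type library the Cabin1 circle was below the filter and not tested. With CIRI2 counts 4 of the 8 calls were lost, those of Fstl5, Fbxo42, Wdr49 and Cabin1, with a log2 fold change of 2.22 for Fbxo42. Within flow cell 1, where 1 library of each mutant cannot test the named calls, the Fbxo42 circle had a log2 fold change of 2.17.

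Among the fixed lists in this comparison, the ependyma and choroid plexus list was called lower (camera p = 3.77e-05, adjusted p = 0.00181), and this was lost with an estimated correlation (adjusted p = 0.692) and with fry (adjusted p = 0.168). Of its 11 measured members 1 fell, Wdr49, and the others passed no test, for example the dynein genes Dnah11 (-0.13 ± 0.27) and Dnah9 (0.02 ± 0.27) and Cfap54 (-0.34 ± 0.35), so its median log2 was -0.31 and its mean -0.63. Without Wdr49 the camera p was 0.363. In the GABAergic list 1 of 24 members rose, Gabra2, and 0 fell, with the synapse scaffold Gphn at 0.15 ± 0.22 and Gabra4 at -0.10 ± 0.22. The camera adjusted p was 0.590.

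In the other lists no member passed the test by edgeR, and camera called none of them. These were the 43 glutamatergic postsynaptic genes (Dlgap1 0.02 ± 0.15, Sipa1l1 -0.25 ± 0.17; 17 higher), the 40 presynaptic genes (Rims2 0.0033 ± 0.14, Rims1 -0.25 ± 0.17; 18 higher) and the 34 voltage-gated channels (Cacna1b 0.36 ± 0.27, Scn8a -0.04 ± 0.16; 22 higher). The 19 hosts of recoding sites (Cadps -0.14 ± 0.24, Grik2 0.18 ± 0.16) had 11 members higher, the 34 splicing and circular RNA regulators (Rbfox1 0.49 ± 0.24, Hnrnpu -0.04 ± 0.25) had 20 and the 11 genes of double-stranded RNA sensing (Tbk1 0.13 ± 0.54, Stat2 0.90 ± 0.88) had 5. Of the 26 abundant hosts 12 were higher, with Zfp609 at -0.15 ± 0.18. Among markers of cells, 12 of 14 of astrocytes (Slc4a4 0.15 ± 0.18), 11 of 18 of oligodendrocyte lineage (St18 0.23 ± 0.19), 5 of 8 of microglia (Mertk 0.14 ± 0.39) and 3 of 9 of endothelial cells (Atp13a5 -0.52 ± 0.76) were higher. Among those of regions, 7 of 10 of cerebellum (Grm4 0.31 ± 0.32), 3 of 7 of striatum (Foxp1 -0.06 ± 0.21) and 7 of 11 of cortex and hippocampus were higher. Of the 3 measured altered genes the hosts Adarb1 (1.26 ± 0.33) and Gria2 (-0.74 ± 0.21) did not pass, and adjusted over the list alone 1 was up and 1 down. Adjusted over the list alone, Gabra2 and Wdr49 were the only calls in the other lists. Median, mean and test differed in sign for the oligodendrocyte list (median 0.12, mean -0.38, test down), the GABAergic list (-0.07, 0.05, up), the abundant hosts (-0.010, 0.03, down) and the striatum list (-0.0077, 0.08, up).

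Adar1-2KO against wild type asked what the loss of nearly all editing activity did together with the Gria2 allele and the lack of Ifih1, which it cannot tell apart. Of 38297 circles, 9 rose and 15 fell, against 9 and 8 with DESeq2 size factors and 9 and 6 with library sizes from mapped reads. The circle of Lrp1b, a large receptor of the LDL receptor family, rose from 142 ± 16.8 to 838 ± 122 CPM, a log2 fold change of 2.56 ± 0.26 (SE, n = 3). An intron circle of Stxbp5, which encodes the SNARE regulator tomosyn, rose from 6.61 ± 3.73 to 331 ± 78.3 CPM (5.64 ± 0.67), and a circle of Zbtb20, a transcription factor of hippocampal development, from 556 ± 38.3 to 1465 ± 188 CPM (1.40 ± 0.20). Circles of Dennd1b, Adarb1, Gabra2, Chchd6 and Fstl5 rose here as in Adar2KO on Illumina. On ONT the Dennd1b and Chchd6 circles had values of -0.28 and 0.40 without passing. Among the falls, 6 of the 15 lay on chromosome 7, led by a circle of the long non-coding gene A230057D06Rik.

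Circles of Dennd1b (236 ± 145 CPM, adjusted p = 5.74e-05), Adarb1 (113.5 ± 65.2 CPM), Gabra2 (88.2 ± 31.7 CPM), Chchd6 (78.4 ± 6.40 CPM) and Atf6 (54.0 ± 35.4 CPM, adjusted p = 0.0422) were listed in none of the wild type libraries. Atf6 encodes a sensor of endoplasmic reticulum stress, and its circle lies on chromosome 1 at 170642992 to 170647001. The edgeR adjusted p was 0.000535 for Adarb1, Gabra2, Chchd6 and Lrp1b (chromosome 2, 40615394 to 40641028), 0.00300 for Stxbp5 (chromosome 10, 9717615 to 9744497) and 0.0184 for Zbtb20 (chromosome 16, 43390044 to 43398111). The Fstl5 circle had 63.5 ± 53.3 CPM (edgeR adjusted p = 0.0192), a ratio of 79.0 to wild type with a 95% counting interval from 33.7 to 244. ONT read it at 23.6 CPM in Adar1-2KO and in neither wild type library, without passing. On ONT the Zbtb20 circle was read at 508 CPM in wild type and in none of the Adar1-2KO libraries, the opposite direction, without passing (edgeR adjusted p = 0.476).

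The A230057D06Rik circle (chromosome 7, 61561111 to 61575168) fell from 251 ± 66.8 CPM (adjusted p = 3.71e-06) and an intergenic circle (chromosome 7, 91275537 to 91276021) from 139 ± 36.5 CPM (adjusted p = 8.41e-05), by edgeR. ONT listed neither circle in any genotype. On Illumina both were listed in none of the Adar1-2KO libraries. Likewise unlisted were the circles of Cabin1, of Wdr49 (75265654 to 75289386, 77.4 ± 43.1 CPM in wild type), of Arsb, a lysosomal sulfatase (chromosome 13, 93926547 to 93930726, 25.8 ± 8.58 CPM), of L3mbtl3, a chromatin reader (chromosome 10, 26178551 to 26228273, 25.1 ± 2.97 CPM) and of the kinase Nek1 (chromosome 8, 61502818 to 61507656, 24.5 ± 2.69 CPM). Another 3 on chromosome 7 were intergenic, at 61841753 to 61843341 (39.4 CPM in wild type), 61840465 to 61843341 (26.4 ± 12.8 CPM) and 61752447 to 61768791 (23.7 ± 1.52 CPM). The other 5 falls were circles of Tanc1, Nudcd3, A230057D06Rik, Cep63, a centrosome protein (40.4 to 0.344 CPM) and Nfatc3, a calcineurin-regulated transcription factor (chromosome 8, 106805236 to 106806373, 193 ± 13.7 to 42.4 ± 13.5 CPM, -2.18 ± 0.37), each with an edgeR adjusted p of 0.0494. ONT read this Nfatc3 circle at 238 CPM in wild type and 178 CPM in Adar1-2KO (-0.43, edgeR adjusted p = 0.844). CIRI2 listed the circle at 61841753 in both Adar1-2KO libraries it covers, with a log2 fold change of -1.04. ONT listed the Cabin1 circle in 3 of the Adar1-2KO libraries, those of L3mbtl3 and Nek1 in 2 and that of Arsb in 1.

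In the interval of chromosome 7 from 61435818 to 61843341, which spans A230057D06Rik and was set out after its values were seen, 38 circles were tested. In Adar1-2KO 5 of them fell, 0 rose, 17 had higher and 21 lower fitted values than in wild type, and 16 were listed in none of the Adar1-2KO libraries. One circle there (61740862 to 61768791) had 52.2 CPM in wild type and 168 CPM in Adar1-2KO without passing, and another (61533001 to 61575168) had 31.8 CPM in Adar1-2KO and was listed in none of the other 6 libraries. ONT listed none of the called circles of this interval.

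**Figure D2:**
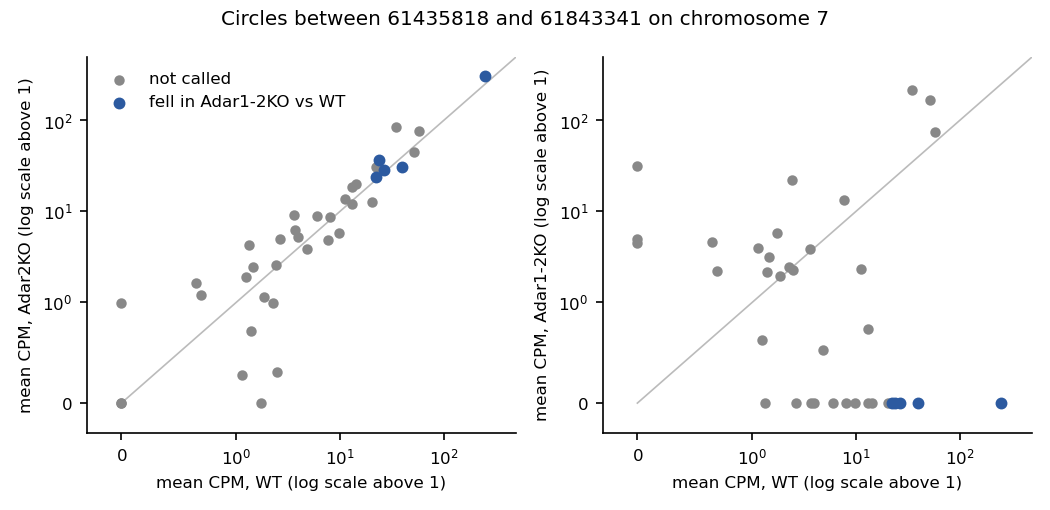
Mean CPM of the 38 tested circles of chromosome 7 between 61435818 and 61843341, wild type (horizontal axis) against Adar2KO (left) and Adar1-2KO (right), on axes that are linear below 1 and logarithmic above, n = 3 libraries per group. The 5 circles in blue, which fell in Adar1-2KO against wild type, had 22.4 to 251 CPM in wild type and 0 in Adar1-2KO.

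Summed per host gene, Chchd6 (5.80 ± 0.72), Gabra2 (2.05 ± 0.18, 607 ± 60.7 CPM in Adar1-2KO) and Zbtb20 (1.43 ± 0.18) rose, with edgeR adjusted p of 0.00379, 0.000192 and 0.00379. Wdr49 (-6.11 ± 0.52), the overlapping Gm13483 and Gm48908 (-3.06 ± 0.51), A230057D06Rik (-3.05 ± 0.27), Arhgap35, a GTPase-activating protein (-2.59 ± 0.30, 144 ± 9.21 to 23.9 ± 3.58 CPM), Ccser2 (-2.41 ± 0.31) and the uridine phosphorylase Upp2 (-1.59 ± 0.24) fell. Their edgeR adjusted p ran from 0.000192 to 0.0475. The calls of Chchd6, Gabra2, Zbtb20, Wdr49, A230057D06Rik and Arhgap35 were kept without any 1 of the libraries. Leaving out libraries does not test the listing of circles on Illumina. The Chchd6 circle, listed there in none of the wild type libraries, had a log2 fold change of 0.40 on ONT without passing. ONT read the called Zbtb20 circle the opposite way without passing, at 508 CPM in wild type and in none of the Adar1-2KO libraries. That of Gm13483 with Gm48908 was lost without any but Adar1-2KO replicate 2 or 3, that of Upp2 without any but Adar1-2KO replicate 1 or 3 and that of Ccser2 without wild type replicate 1 (edgeR adjusted p up to 0.241, 0.115 and 0.0572). Values that did not pass were Nectin3, an adhesion protein (1.33 ± 0.25), Stard3nl (3.04 ± 0.63) and the sodium-calcium exchanger Slc8a3 (-1.07 ± 0.22). Among circles, those of Nectin3 (1.56 ± 0.27) and 2 longer of Gabra2 (1.65 ± 0.28 and 2.31 ± 0.41) did not pass.

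At an unadjusted p under 0.05 stood 2583 of 38297 circles and 674 of 8650 host genes, where evenly spread p would give a share of 0.05. DESeq2 called 190 circles and 52 host genes. Of the 24 circles 18 were listed in none of the libraries of 1 group. The count ran from 8 without wild type replicate 2 to 46 without Adar1-2KO replicate 3, and the calls of Dennd1b, Adarb1, Gabra2, Chchd6, Lrp1b, Stxbp5, A230057D06Rik and the circle at 91275537 were kept without any 1 of the 9 libraries, while Zbtb20 lost its call without Adar1-2KO replicate 1 or 2 or any wild type library (edgeR adjusted p up to 0.153). The call of Atf6 was lost without any 1 library, those of Cabin1 and Wdr49, not tested without a wild type library, without Adar1-2KO replicate 1 or 2, that of Fstl5 without any but Adar2KO replicate 2 or Adar1-2KO replicate 2 or 3, that at 61841753 without Adar2KO replicate 1 or 3 or wild type replicate 2 or 3, and those of Arsb, L3mbtl3, Nek1 and the circles at 61752447 and 61840465 without any but Adar1-2KO replicate 3 (edgeR adjusted p up to 0.199, 0.0812, 0.192, 0.112 and 0.218). With CIRI2 counts 9 of 19 named calls were lost, those of Atf6, Fstl5, Cabin1, Wdr49, Arsb, Nek1 and the circles at 61841753, 61840465 and 61752447. The count of host genes ran from 7 to 20, the highest without Adar1-2KO replicate 3. Within flow cell 1 there was 1 library of each mutant, which cannot test the named calls. Log2 fold changes over all alternatives, these libraries included, ran from 2.34 to 2.90 for Lrp1b and from 5.05 to 5.95 for Stxbp5.

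Among the lists in this comparison none was called by camera, whose lowest adjusted p was 0.190 for the GABAergic list and for the splicing regulators. In the GABAergic list 1 of 24 members rose, Gabra2, with Gphn at 0.50 ± 0.22 and Gabra4 at -0.05 ± 0.22. In the ependyma and choroid plexus list 1 of 11 fell, Wdr49, with Cfap54 at 0.69 ± 0.35 and Dnah9 at -0.47 ± 0.28. No member of the other lists passed by edgeR. The hosts of recoding sites had 11 of 19 members higher (Grik1 0.43 ± 0.26, Unc80 -0.08 ± 0.18), the splicing regulators 19 of 34 (Celf2 0.39 ± 0.19, Khdrbs3 -0.15 ± 0.18) and the genes of double-stranded RNA sensing 5 of 11 (Tbk1 -0.67 ± 0.55, Rnf213 -0.86 ± 1.24). Postsynaptic genes had 21 of 43 higher (Sipa1l1 -0.59 ± 0.17, Nlgn1 0.15 ± 0.20), presynaptic genes 20 of 40 (Rims2 0.28 ± 0.14, Rims1 -0.29 ± 0.17), channels 13 of 34 (Kcnt2 0.59 ± 0.28, Cacna1a -0.27 ± 0.21) and abundant hosts 5 of 26 (Zfp609 -0.39 ± 0.18).

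Markers of astrocytes in Adar1-2KO had 8 of 14 members higher (Trpm3 0.36 ± 0.22), those of oligodendrocyte lineage 11 of 18 (Pcdh15 0.39 ± 0.30), of microglia 6 of 8 (Ikzf1 3.19 ± 1.31) and of endothelial cells 4 of 9 (Flt1 3.02 ± 1.32). Markers of cerebellum had 7 of 10 higher (Grm4 -0.61 ± 0.32), of striatum 5 of 7 (Meis2 1.49 ± 0.45) and of cortex and hippocampus 7 of 11 (Prox1 -1.08 ± 0.50). The altered genes Adarb1 (1.43 ± 0.33), Gria2 (-0.83 ± 0.21) and Adar (-1.23 ± 0.75) did not pass as hosts. Adjusted over the list alone, 1 member was up in each of the ependymal, GABAergic, altered, presynaptic, splicing and striatum lists, and 1 was down in each of the ependymal, altered, recoding and abundant lists. Median, mean and test differed in sign for double-stranded RNA sensing (-0.27, 0.27, down), endothelial (-0.31, 0.72, up), ependymal (0.01, -0.61, down), presynaptic (-0.0044, -0.11, up) and recoding hosts (0.13, -0.0023, up).

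Adar1-2KO against Adar2KO asked what the altered Adar and the lack of Ifih1 together added to the changes of Adar2KO. On Illumina 2 circles were higher in Adar1-2KO and 6 lower. This balance was 2 and 2 with library sizes from mapped reads or at least 10 reads, and 263 and 106 with no filter. The Stxbp5 intron circle rose (5.30 ± 0.66, SE, n = 3) and so did the Lrp1b circle (2.44 ± 0.26, 155 ± 26.4 to 838 ± 122 CPM), with edgeR adjusted p of 0.00998 and 0.00203. The Fbxo42 circle fell (-2.40 ± 0.31, edgeR adjusted p = 0.0121). The A230057D06Rik circle fell from 308 ± 37.7 CPM to being listed in none of the Adar1-2KO libraries (edgeR adjusted p = 2.94e-06).

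Also unlisted in Adar1-2KO were the circles on chromosome 7 at 91275537 (96.5 ± 19.9 CPM in Adar2KO), 61752447 (36.7 ± 5.05 CPM) and 61841753 (30.8 ± 8.36 CPM), and that of L3mbtl3 (32.2 ± 7.18 CPM), with edgeR adjusted p of 0.000198, 0.0311, 0.0311 and 0.0415. Values that did not pass were circles of Zbtb20 (1.14 ± 0.20), of the ubiquitin ligase gene Fancl (4.43 ± 0.87), of the coactivator Ncoa2 (1.64 ± 0.34), of Trpc6 (2.33 ± 0.48), and, lower, of Nfatc3 (-2.31 ± 0.37) and Cep63 (-6.83 ± 1.11). With CIRI2 counts Trpc6 and Nfatc3 had -0.11 and 0.021, the opposite direction. Circles of Rere, Nudcd3 and Nek1 also did not pass. As hosts, Zbtb20 rose (1.22 ± 0.18, edgeR adjusted p = 0.0267) and A230057D06Rik (-3.26 ± 0.27), Arhgap35 (-2.54 ± 0.30) and Fbxo42 (-2.34 ± 0.30) fell, with edgeR adjusted p of 0.00021, 0.00735 and 0.00995. On ONT the Zbtb20 circle had a log2 fold change of -8.67 between the mutants, the opposite direction, without passing.

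At an unadjusted p under 0.05 stood 2442 of 38297 circles and 575 of 8650 host genes, where evenly spread p would give a share of 0.05. DESeq2 called 183 circles and 38 host genes. Of the 8 circles 5 were listed in none of the Adar1-2KO libraries. The count ran from 3 without Adar2KO replicate 1 to 28 without Adar1-2KO replicate 3, and Stxbp5 lost its call without Adar1-2KO replicate 1 or 2 or Adar2KO replicate 1 and Fbxo42 without Adar1-2KO replicate 1 or any Adar2KO library (edgeR adjusted p up to 0.113 and 0.104). The calls of L3mbtl3 and of the circles at 61752447 and 61841753 were lost without any but Adar1-2KO replicate 3 (up to 0.223), as was that of Zbtb20 as a host (up to 0.199), while Arhgap35 lost its call without Adar2KO replicate 1 (0.0709) and Fbxo42 as a host without that library, Adar2KO replicate 2 or Adar1-2KO replicate 1 (up to 0.0893). The count of host genes ran from 1 without Adar2KO replicate 1 to 13 without Adar1-2KO replicate 3. Within flow cell 1, with 1 library of each mutant and the spread taken from wild type, 4 circles were called, which does not test the named calls, with log2 fold changes of 2.10 for Lrp1b, 4.67 for Stxbp5 and -1.82 for Fbxo42.

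No list was called between the mutants, with camera adjusted p of 0.352 or more, and no member of any list passed by edgeR, nor when adjusted over the list alone. Abundant hosts had 5 of 26 members higher in Adar1-2KO, channels 10 of 34 (Scn8a 0.16 ± 0.16), hosts of recoding sites 7 of 19, splicing regulators 19 of 34 and double-stranded RNA sensing genes 4 of 11. Postsynaptic genes had 25 of 43 higher, presynaptic genes 19 of 40 (Erc1 -0.19 ± 0.26) and GABAergic genes 15 of 24 (Gabra2 0.16 ± 0.18). Markers had 8 of 14 higher for astrocytes, 11 of 18 for oligodendrocyte lineage, 5 of 8 for microglia, 5 of 9 for endothelial cells, 6 of 11 for ependyma (Cfap54 1.03 ± 0.36), 5 of 10 for cerebellum (Grm4 -0.92 ± 0.33), 5 of 7 for striatum (Meis2 1.28 ± 0.44) and 5 of 11 for cortex and hippocampus. Of the altered genes 1 of 3 was higher (Adarb1 0.17 ± 0.32). Median, mean and test differed in sign for astrocytes (0.06, -0.32, down), double-stranded RNA sensing (-0.58, 0.53, down), cortex and hippocampus (-0.09, 0.07, up), postsynaptic (0.02, -0.08, up), presynaptic (-0.04, -0.09, up) and recoding hosts (-0.03, -0.23, up).

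The ONT libraries read the same kind of cDNA on long reads. In Adar2KO against wild type 1 circle of 10367 rose, that of Fbxo42, from 98.8 ± 0.168 (SD, n = 2) to 1265 ± 190 CPM (SD, n = 3), a log2 fold change of 3.67 ± 0.30 (edgeR adjusted p = 0.00118). In Adar1-2KO against Adar2KO 36 circles rose and 13 fell. The circle of Nalcn, the sodium leak channel, rose from 173 ± 10.1 to 1055 ± 214 CPM (edgeR adjusted p = 0.00166), and those of Lrp1b (3.30 ± 0.37) and Stxbp5 (4.64 ± 0.77) rose as on Illumina. The Fbxo42 circle fell from 1265 ± 190 CPM to 139 ± 17.7 CPM (-3.18 ± 0.24, edgeR adjusted p = 0.000515).

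Other large rises on ONT between the mutants were circles of Copa, a coat protein of Golgi vesicles (3.60 ± 0.51), Mllt10 (2.94 ± 0.34), Faf1 (2.63 ± 0.41), the RNA-binding Rbms1 (2.58 ± 0.44), the endocytic kinase Aak1 (2.46 ± 0.37), Ccar1 (2.45 ± 0.26) and a Nfatc3 circle at 106825704 to 106827621 (2.36 ± 0.26). The other 26 rises lay between 1.18 (Ttc3) and 2.35 (Erc1). A circle antisense to Ppia, circles of Plcl1 and Ubn2 and a circle antisense to Stk32c fell from 155 ± 62.7, 128 ± 48.5, 93.7 ± 15.1 and 73.2 ± 16.4 CPM to being listed in none of the Adar1-2KO libraries. Those of the neuronal splicing factor Nova2 (-2.46 ± 0.41), H6pd (-1.88 ± 0.28), Cnksr3 (-1.78 ± 0.31), Ralgps1 (-1.77 ± 0.32) and Ptchd4 (-1.69 ± 0.26) fell, as did those of Sel1l3, Ppp1cb and Gpr137c, from -1.56 to -1.39. The calls of Fbxo42, Lrp1b, Mllt10, Nalcn, Ccar1 and Nfatc3 were kept without any 1 of the 8 libraries, those of Plcl1 and Ppia were lost without Adar2KO replicate 2 (edgeR adjusted p up to 0.0599), and those of Stxbp5, Aak1, Rbms1, Nova2, Cnksr3, Ralgps1 and Stk32c without any but Adar1-2KO replicate 3 (up to 0.216). Those of Copa, Faf1, H6pd, Ubn2 and Ptchd4 were lost without any 1 Adar2KO library and without 1 to 3 others (edgeR adjusted p up to 0.181).

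In Adar1-2KO against wild type on ONT 0 circles passed by edgeR, with 759 at an unadjusted p under 0.05 and 47 called by DESeq2. Lowest in p were the circles of Plcl1 and antisense to Ppia, both with an edgeR adjusted p of 0.0714, and Lrp1b had a value of 2.53 ± 0.43, Mllt10 2.42 ± 0.40, and the Gabra2, Adarb1 and Stxbp5 circles 111, 100.2 and 250.4 CPM against none listed in wild type. Circles of Ubn2, Specc1l and Stk32c, at 126, 82.6 and 57.0 CPM in wild type, were listed in none of the Adar1-2KO libraries without passing. In Adar2KO against wild type, values that did not pass were circles of Med13l (1.38 ± 0.29), Cpeb3 (1.78 ± 0.39), Nalcn (-1.39 ± 0.25), Fbxw7 (-1.50 ± 0.28), Ccar1 (-1.36 ± 0.28), Mettl6 (-1.08 ± 0.23) and Gm42339 (-1.06 ± 0.23), with Adarb1 and Gabra2 at 116 and 91.4 CPM against none listed. At an unadjusted p under 0.05 stood 436 of 10367 circles in Adar2KO against wild type, below a share of 0.05, and 1080 between the mutants, above it. DESeq2 called 11 and 189. The count between the mutants ran from 8 without Adar2KO replicate 2 to 119 without Adar1-2KO replicate 3, and the Fbxo42 call in Adar2KO against wild type was lost without either wild type library (edgeR adjusted p up to 0.147).

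**Figure D3:**
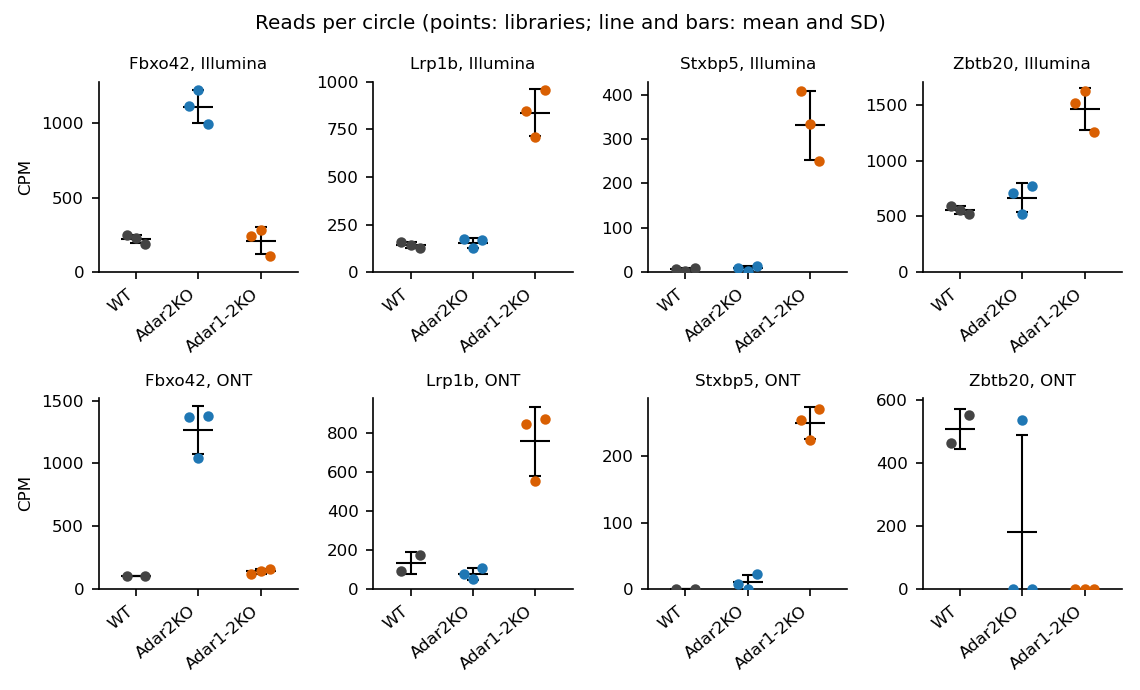
CPM per library (points) with mean and SD (bars) of the circles of Fbxo42, Lrp1b, Stxbp5 and Zbtb20 on Illumina and ONT, by genotype, n = 3 except n = 2 for wild type on ONT. The Fbxo42 circle had mean CPM of 1112 on Illumina and 1265 on ONT in Adar2KO, the Lrp1b circle 838 and 759 in Adar1-2KO, and the Zbtb20 circle 1465 on Illumina and 0 on ONT in Adar1-2KO.

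Of the circles called on Illumina and tested on ONT, 6 of 7 had the same sign in Adar2KO against wild type, 12 of 14 in Adar1-2KO against wild type and 4 of 4 between the mutants. The circles of Fbxo42 in the first, and of Lrp1b, Stxbp5 and Fbxo42 in the last, were called on both platforms. Libraries with the same replicate number carry the same sample name on both platforms, so this is agreement of the measurement and not of further animals. The same sign did not mean the same size. In Adar2KO against wild type the Chchd6 circle had 0.46 on ONT and 10.6 on Illumina, while in Adar1-2KO against wild type the Lrp1b circle had 2.53 and 2.56. Across the 8991 circles tested on both, which are not independent replicates, log2 fold changes had Pearson's r of 0.133, 0.366 and 0.446 and Spearman correlations of 0.139, 0.500 and 0.525 for the 3 comparisons in that order. With at least 20 reads per library, r was 0.199, 0.464 and 0.433. Without Adar1-2KO replicate 3 on both platforms, a fit chosen after the data were seen, r was 0.155, 0.248 and 0.223.

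The circular share was compared to relate each circle to forward-spliced RNA at the same sites. RNase R removes part of the linear RNA, so the share cannot fully tell a change of the circle from one of all transcripts of its gene. By limma, 1 circle of 6353 changed in Adar2KO against wild type, that of Rmdn2 (chromosome 17, 79957731 to 79980002, adjusted p = 0.0422). Its back-splice reads were 85, 63 and 40 in wild type and 53, 70 and 61 in Adar2KO, and its forward-splice reads 728, 218 and 149 against 0 in all 3. In Adar1-2KO against Adar2KO circles of Rmdn2, Nek1, Arhgef7, Grid1 and Tdrd3 fell in share, each with a limma adjusted p of 0.0432 and 0 forward-splice reads in all Adar2KO libraries. Of the 6353 circles, 32.4% to 38.2% had 0 forward-splice reads in each library, except for 16.8% in Adar1-2KO replicate 3. In Adar1-2KO against wild type limma called 0, with 306 circles at an unadjusted p under 0.05, and no other tool was run on shares. In the other two comparisons 183 and 338 circles stood there. Evenly spread p would put a share of 0.05 of the 6353 circles there, which only the 338 exceeded. With 1 library left out the count for Adar2KO ran from 0 without wild type replicate 2 or Adar1-2KO replicate 2 to 10 without Adar1-2KO replicate 3, and the other two went up to 60 and 67 without Adar1-2KO replicate 1.

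The mutants were set against each other for a shared response. The 6 circles called in both against wild type were those of Dennd1b, Gabra2, Adarb1, Chchd6 and Fstl5, which rose in both, and of Cabin1, which fell in both. On ONT, libraries of the group that Illumina left unlisted held 82 reads of the Dennd1b circle and 7 of the Chchd6 circle in wild type, and 96 and 32 of the Cabin1 circle in Adar2KO and Adar1-2KO. Independent lists of these sizes would share 0.00141 rises and 0.000783 falls. Both comparisons use the same 3 wild type libraries, which cannot be split into parts of 2. All 9 Illumina libraries, wild type included, were also drawn 40 times with no difference between genotypes. The mutants of these draws shared 1.68 calls on average and 6 at most. These simulated groups had 7.38 and 6.05 calls on average, and 13 and 15 at most. The log2 fold changes of the mutants had a covariance of 1.08, below the 1.60 of the simulated groups, and r = 0.404 against 0.512.

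In the authors' deposited tables, 46 circles (26 up, 20 down) had an adjusted p under 0.05 for Adar2KO and 54 (20 up, 34 down) for Adar1-2KO. All 46 had the same direction here, and of 53 of the 54 tested here 51 did. All 8 circles called here for Adar2KO were among them, and 20 of the 24 for Adar1-2KO. The authors' log2 fold change was 2.24 ± 0.54 for the Fbxo42 circle (DESeq2 adjusted p = 0.0263) and 5.41 ± 0.92 for that of Stxbp5 (5.19e-05). Lrp1b at 2.34 ± 0.83 and Zbtb20 at 1.44 ± 0.82 did not pass there (both 0.911). Base means recomputed from the counts matched the authors' within 1% for 772 of 772 circles of the Adar2KO table. For the Adar1-2KO table they matched for 157821 of 157821 circles when Adar1-2KO replicate 3 was left out and for 681 when it was kept.

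**Figure D4:**
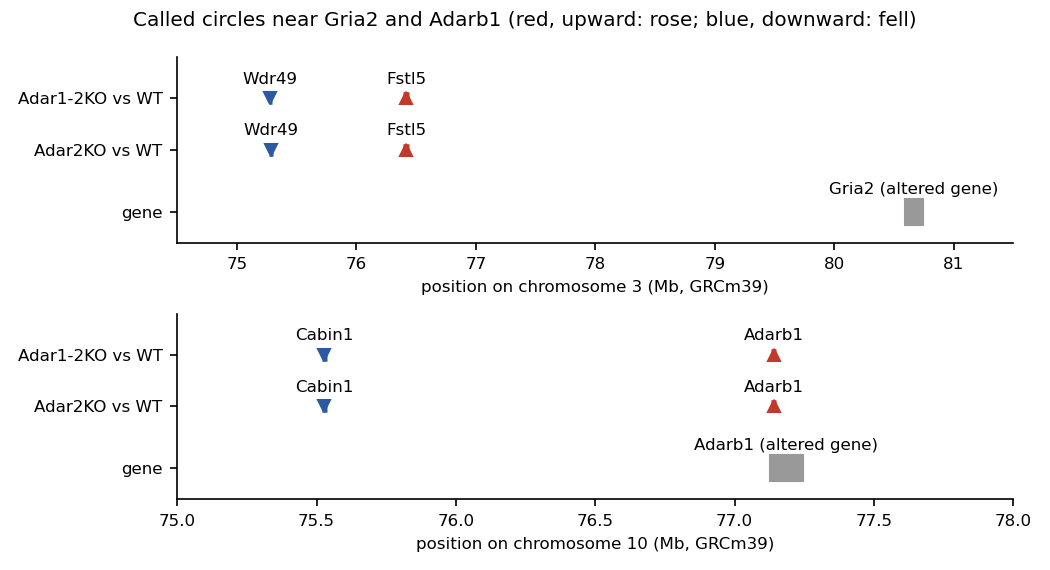
Positions of called circles and of the altered genes on chromosomes 3 and 10 (horizontal axis, position on GRCm39 in megabases), for both mutants against wild type, with rises and falls marked. Circles of Wdr49 and Fstl5 lay near Gria2, and that of Cabin1 near Adarb1, each within 10 Mb.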

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

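The fit of features listed in every library, that of libraries of 1 flow cell and platform agreement with 1 library left out were chosen after the data were seen. Counts are given below in the order Adar2KO against wild type, Adar1-2KO against wild type and Adar1-2KO against Adar2KO. Of values of named circles, host genes and lists under the alternatives set beforehand, 1831 kept direction and side of the threshold, 353 lost their call, 180 gained one and 2 turned direction. Under the fits added later 102 kept both, 26 lost their call and 8 gained one. The 1831 and 102 include named values that did not pass as reported and stayed so. The share of calls that were lost is therefore higher than these counts give. The cause of these moves was not tested, except that fewer libraries or fewer features enter some fits.

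For circles on Illumina, with 8, 24 and 8 calls as reported, a threshold of 0.1 gave 11, 33 and 20 and DESeq2 34, 190 and 183. DESeq2 size factors in edgeR gave 8, 17 (9 up, 8 down) and 8, library sizes from mapped reads 8, 15 (9 up, 6 down, against 9 up and 15 down as reported) and 4. At least 10 reads gave 4, 18 and 4, no filter 98, 423 and 369, 2 genotypes only 19, 9 and 4, the replicate block 8, 20 and 5 and CIRI2 counts 5, 24 and 26, where 4 of 8, 9 of 19 and 1 of 8 named calls were lost. Features listed in every library gave 4, 7 and 4, and libraries of 1 flow cell 1, 3 and 4. Leaving out 1 library gave 4 to 20, 8 to 46 and 3 to 28, each highest without Adar1-2KO replicate 3. The circles of Dennd1b, Adarb1, Gabra2 and Chchd6 kept their calls against wild type in all 17 settings in which they were run. Each of these settings took 0 reads for wild type, where CIRI2 too listed none of these circles, so they do not test the listing itself. ONT had 82 reads of the Dennd1b circle and 7 of the Chchd6 circle in wild type. The circle of Trpc6 (9, 8634048 to 8658378) had a log2 fold change of -0.11 between the mutants with CIRI2 counts, against 2.33, and that of Nfatc3 (8, 106805236 to 106806373) one of 0.021, against -2.31.

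For host genes, with 6, 9 and 4 calls, a threshold of 0.1 gave 10 between the mutants, DESeq2 15, 52 and 38, mapped reads 4, 5 and 3, no filter 25, 181 and 153, 2 genotypes only 9, 5 and 1, and leaving out 1 library 2 to 11, 7 to 20 and 1 to 13. For ONT circles, with 1, 0 and 49 calls by edgeR, a threshold of 0.1 gave 1, 3 and 61, DESeq2 11, 47 and 189, no filter 83, 115 and 197, 2 genotypes only 1, 0 and 20 and the replicate block 2, 1 and 28. Features listed in every ONT library gave 1, 3 and 211, and leaving out 1 library 0 to 1, 0 to 2 and 8 to 119. For the circular share, with 1, 0 and 5 calls by limma, at least 50 reads gave 1, 0 and 1, the replicate block 0, 0 and 0, and leaving out 1 library 0 to 10, 0 to 60 and 0 to 67. The numbers of the replicates did not pair the libraries: correlations of libraries with the same number, after removal of genotype means, ran from -0.0295 to 0.018.

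Median log2 fold changes of circles were 0.04, -0.26 and -0.31 with TMM and 0.16, 0.07 and -0.10 with mapped reads, and those of host genes 0.02, -0.06 and -0.10 against 0.20, 0.31 and 0.09. Platform agreement in r was 0.199 and 0.464 against wild type with at least 20 reads, and 0.399 for Adar1-2KO against wild type and 0.468 between the mutants for ends within 5 bases. With the same library left out on both platforms it ran from 0.0906 to 0.158, 0.246 to 0.412 and 0.223 (without Adar1-2KO replicate 3) to 0.483. The call of the ependymal list, 1 list, was 0 with an estimated correlation and with fry (adjusted p = 0.168). In the alternative fits that called it with camera at the preset correlation, its adjusted p ran from 0.00038 to 0.037. With 1 library left out, Adar2KO less wild type ran from -2623 (without wild type replicate 3) to 8626 circles and from -0.345 (without wild type replicate 2) to 1.67 percentage points of median circular share. Adar1-2KO less wild type ran from -1.06 to 2.14 for exon circles, -1.10 to 0.479 for intron and -0.845 to 0.493 for intergenic circles, each turned without Adar1-2KO replicate 3. Thinning to the smallest library fixes the reads over mapped reads, so it was void for that value. Flanking complementarity was not run. In simulated counts with the depth and spread of these libraries 1% of circles changed 4-fold and 24% of those changed 16-fold were called, and depth was not varied apart from spread.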

Other observations

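The tests of sequencing depth, of the Illumina flow cells and of the genotype for Adar1-2KO replicate 3, all tests of unlisted circles and of circles near the altered genes, and those of ependymal cells other than the test without Wdr49 were chosen after the result was seen.

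Some circles abundant on ONT were missing from single Illumina libraries. Of 1828 circles with at least 10 reads in all 8 ONT libraries, 1676 were listed in all of the same 8 on Illumina, 102 in some only and 50 in none. A circle of Ankrd12 (chromosome 17, 66331071 to 66360086), a gene of an ankyrin repeat protein, had 22129, 27573 and 57373 reads in Adar2KO replicates 1 and 2 and Adar1-2KO replicate 3 and was not listed in the other 6, while ONT read it 1906 to 7255 times in each library. CIRI2 gave 131, 232 and 326 reads in those 3. A circle of the kinase Tlk1 had 1526 to 3805 reads in 8 Illumina libraries and was not listed in Adar1-2KO replicate 2, where ONT had 189 reads. Both circles were picked after their values were seen.

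Adar1-2KO replicate 3 listed few circles for its reads on both platforms. At equal numbers of back-splice reads it listed 20240 circles against 54244 to 67702 in the others on Illumina, which argues against the depth of such reads. At equal numbers of ONT reads it listed 19764 against 22347 to 37778, which argues against the Illumina flow cells as the whole cause. The 2 other Adar1-2KO libraries were within the range of the 6 of other genotypes, which argues against the genotype as the whole cause. Its deviations per circle had r = 0.734 between the platforms, against 0.0672 to 0.274 for other libraries, so few molecules before the cDNA was amplified is a candidate explanation. The yield of RNA and a difference of this brain stay open as untested.

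Of 20 cases of a called circle that 1 genotype group did not list on Illumina, ONT listed 9 in that group, and 4 of 7 tested on ONT, circles of Chchd6, of Nudcd3 and of Cabin1 in both mutants, had a log2 fold change within 1 of 0, so a listing step of the Illumina caller may explain these 4. ONT had 82 reads of the Dennd1b circle in wild type, where 113 were due from its level elsewhere. Its ONT log2 fold change was 1.09 in Adar2KO and -0.28 in Adar1-2KO against wild type, against 12.3 and 12.2 on Illumina. For this circle these values argue against the absence from wild type that Illumina gave, while a smaller rise in Adar2KO stays open. On ONT the circles of L3mbtl3 and Tanc1 had -2.74 and -3.16, the direction of their calls. For 4 of 5 that ONT listed elsewhere only, those of Adarb1, Gabra2 and Wdr49 (2 circles), ONT was due at least 10 reads in the group and listed none, but these were picked for 0 ONT reads and ONT too left out the Zbtb20 circle in Adar1-2KO, so this does not tell. Called circles also lay within 10 Mb of the altered genes more often than other tested circles, 3 of 7 for Adar2KO (Cabin1 near Adarb1, Fstl5 and Wdr49 near Gria2; two-sided Fisher's exact p = 0.000132) and 4 of 23 for Adar1-2KO (also Tanc1 near Ifih1; p = 0.00414), with the Adarb1 circle left out and p from 0.000937 to 0.0297 at 5 and 20 Mb. Sequence of another strain carried along with the altered genes may explain these, while an effect of the altered genes on their neighbours stays open as untested, and for Cabin1 a listing step too.

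The fall of the ependymal and choroid plexus list in Adar2KO rested on few members. Of 11 members 7 were lower, which does not tell fewer such cells from other causes. Without Wdr49 the camera p was 0.363, so Wdr49 alone may carry it. The other 10 members had a median log2 fold change of -0.22 (from -1.29 to 0.71), far from the fall of Wdr49, which argues against fewer ependymal cells as the cause of that fall. Wdr49 lies near Gria2, and a biological cause stays open as untested.

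Part of the excess of 6 shared calls of the mutants may come from shared controls, which cannot be split. At a threshold of 0.1, 11 and 33 circles were called and 9 were shared, against 2.40 on average and 7 at most in simulated groups with no difference. At 0.05 such groups had 7.38 and 6.05 calls on average and 13 and 15 at most. The 8 circles for Adar2KO lie within this range and the 24 for Adar1-2KO above it. Simulated log2 fold changes covaried more than the real ones (1.60 against 1.08), so their spread differs from that of the data. Other splits of the real libraries gave at most 1 and 2 calls. The simulations therefore do not settle whether either count exceeds that of unchanged groups. This bears on the counts and not on single circles. Of the 6 shared circles, ONT read those of Dennd1b, Chchd6 and Cabin1 in the groups that Illumina did not list, so listing on Illumina may also add to the overlap.

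Splits of the same 6 libraries into other groups number 10 with the real one, which allows no share under 0.05. For circles on Illumina the real split gave 8, 24 and 8 calls in the order used above and the highest other split 1, 2 and 2, for host genes 6, 9 and 4 against 1, 2 and 1 and for ONT circles between the mutants 49 against 2, with 1 split as large in each, the real one. For gene lists they gave 1, 0 and 0 against 0, 1 and 0, with 1, 10 and 10 splits as large. For the circular share they gave 1, 0 and 5 against 4, 51 and 7, with 9, 10 and 6 splits as large. A split that calls 51 where the real one calls 0 points to a structure of the samples, which was not tested further. The 3 wild type libraries came from flow cell 1 on Illumina, as did Adar1-2KO replicate 2 and most reads of Adar2KO replicate 3. The Gabra2 and Adarb1 circles, listed in none of the wild type libraries, had 131 and 134 reads in the former and 276 and 236 in the latter.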
